A study of Mus musculus with 6 samples.

How the data were processed

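The series measured microRNAs (miRNAs, short regulatory RNAs of which each hairpin precursor can give a 5p and a 3p strand, or arm) in 3 kinds of tissue macrophage of adult male C57BL/6J mice: microglia from the brain, macrophages of the colon and macrophages of the liver, also called Kupffer cells. Per the labels, cells were freshly sorted by flow cytometry, all isolation was done within 5 h, total RNA was extracted with a column kit, and 100 ng of it was labelled with Cy3 for 1-colour Agilent miRNA arrays. Microglia were gated as intermediate for CD45 and positive for CD11b and F4/80, without Ly6C or Ly6G. Colon macrophages were gated as positive for CD45, CD11b, CD11c and CD64 and negative for Ly6C, and liver macrophages as positive for CD45, CD11b, F4/80, CD64 and MHC class II. The sample labels give an age of 6 weeks and the design text a range of 6 to 8 weeks. There were 2 arrays per group, 6 in all, and per the design text each array held RNA pooled from 4 to 6 mice, so that the replicates are separate pools and their spread covers differences between pools as well as technical noise. Nothing in the labels ties replicate numbers across groups to a shared day, cage or mouse, and no test treated them as pairs except as an alternative.

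Each array's deposited table holds, per the file headers, 1 line per miRNA with a total gene signal, the error of that signal and a detection flag. The signal is an intensity on a linear scale that the authors deposited as the scanner software wrote it, with values of 0.1 standing for miRNAs that were not detected. Per the submitters' processing notes the software was Agilent Feature Extraction 9.1. The tables hold no spots, background signals, slide numbers or scan dates, so neither a normexp background correction nor a slide or scan block was run. The authors also deposited a value table of 595 miRNAs, which is on a log2 scale: its values reach 16.08, all 6 of its columns have a median of 3.72, and over the miRNAs detected on all arrays it correlated with the log2 signals used here at r = 0.992 across miRNAs and arrays. Its 1410 zeros all belong to miRNAs not detected on that array. All its columns share the same quartiles and maximum, as quantile normalization would give, but how it was normalized is not given in the sources used here, and it served as an alternative only.

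Each array had 1247 mouse miRNAs after 21 control rows were left out. Because only 24.1% to 32.3% of them were detected per array, each array was divided by its 75th percentile over the 248 miRNAs detected on all 6 arrays and multiplied by the mean of these percentiles. A single floor of 3.12 scaled units, the median over arrays of the lowest detected signal (1.64 on the log2 scale), was then set and log2 taken. Levels are given as log2 scaled signal, mean ± SD over 2 arrays, and levels were compared between groups within a miRNA. Signals of different miRNAs were ordered to choose which to name and to split miRNAs at the median level, since brightness also depends on the probe. A miRNA detected on neither array of a group has only a bound there. Its fold is given as at least N-fold. This sets the mean of the brighter group against the mean, over the dimmer group's arrays, of the lowest detected signal of each array. On some arrays, those of the liver among them, the lowest detected signal lay under the common floor, so that a bound can exceed the fold that the floored log2 values give.

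Differences were tested with limma 3.58.1 in R 4.3.3: 1 model of 3 group means over all 6 arrays, moderated by eBayes (3 residual and 2.20 prior degrees of freedom), 2-sided, with Benjamini-Hochberg adjustment within a comparison over the miRNAs detected on both arrays of at least 1 of its 2 groups. All adjusted p-values of single miRNAs are limma's, and the threshold was 0.05. A group not detected on either array stood at the floor with an SD of 0, which comes from the floor and lowers the pooled spread of that miRNA. Standard errors and p-values for such miRNAs may be too small: miR-3106-5p had an SD of 1.63 in microglia but an SE of 0.75 for its change. Over the 3 comparisons 414 miRNAs were tested. Of the 1247 miRNAs 1216, and of the 414 tested ones 396, had a miRNA gene of the same name in the RefSeq table of assembly GRCm38.p6, which was used for names and for the genes whose span holds a miRNA gene. That table gives no strand, so whether host and miRNA lie on the same strand was not checked.

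Before the data were examined, 19 lists were fixed: marker miRNAs of neurons, oligodendrocytes, epithelia, hepatocytes, endothelium, smooth muscle and fibroblasts, erythrocytes and platelets, lymphocytes and myeloid cells, miRNAs that respond to inflammation, miRNAs reported in microglia by earlier studies, and the let-7, miR-17-92, miR-99, miR-100, miR-125 and miR-10, miR-15/16, miR-29, miR-30, miR-181 and Dlk1-Dio3 cluster families. Some miRNAs stand in more than 1 list: 3 members of the epithelial list on the array are in another list, as are 3 of the hepatocyte list, 2 of the endothelial list, 2 of the lymphocyte list and 3 of the microglia list. Lists matched exact stems, which misses such names as miR-21a, miR-145a, miR-1a, miR-195a and miR-181a-1, so the counts of list members leave these out. Of them miR-21a, miR-145a and miR-1a are named here after their values were seen. Lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, 2-sided, adjusted over all lists and comparisons together, and again with an estimated correlation. None of the calls made at the preset correlation held with an estimated one.

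The miRNAs named were fixed by a rule set at the same time. In each comparison they are, among those past the threshold whose groups' arrays do not overlap, the 8 per direction with the largest change among those detected on all 4 arrays, and the 4 per direction with the brightest mean among those detected on both arrays of one group and neither of the other. For miRNAs higher or lower in microglia than in both other populations, the 12 higher and 6 lower ones whose smaller change was largest were taken, the lower ones from those detected on all 6 arrays. Had fewer than 5 passed in a direction, the 5 with the smallest p would have been given. List members may be named as well, and any other is said to be chosen after its values were seen.

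The overlap of the microglia comparisons was set beside that of independent lists and beside 100 simulated data sets with no group effect. The fit and its calls, but not the scaling, were tested on simulated data whose spread was drawn from the fitted prior. This took 10 draws of 414 miRNAs with 200 changed between microglia and the other groups. Changes went up or down at random and errors were independent, so the shares below leave out errors from scaling or whole arrays. For microglia against colon macrophages the fit called 29.9%, 75.3% and 84.8% of true log2 changes of 1, 2 and 3, and 2.36% of its calls were false. Against liver macrophages these shares were 26.0%, 76.2% and 84.9%, with 2.23% false, and between colon and liver macrophages, where nothing was changed, 0 calls were made. Alternatives covered the scaling (75th percentile over all miRNAs, median, quantile normalization, none, the authors' value table), the floor, the filter on detection, eBayes with trend and robust settings, a fit of only the 2 groups compared, a minimum of 2-fold, the replicate number as a block and each array left out in turn. Scaling on 4 spike-in control rows was added after the data were seen.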

Results

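miRNA levels were measured on 6 arrays, 2 each for microglia, colon macrophages and liver macrophages of adult mice, to find miRNAs that mark microglia of the healthy adult brain among tissue macrophages. Of 1247 mouse miRNAs on each array, 300 and 330 were detected in the microglia replicates, 403 and 352 in colon macrophages and 386 and 389 in liver macrophages. The group means were 315 ± 21.2, 377.5 ± 36.1 and 387.5 ± 2.12 miRNAs (SD, n = 2). Both microglia arrays had fewer detected miRNAs than the other 4 arrays, a split with an exact permutation p of 0.0667 (2-sided), the smallest that the 15 splits of 6 arrays allow. On every array all detected miRNAs had a signal above 3 times its error, and the median detected signal was 10.5 to 11.3 times its error. The number of arrays, 2 per group, limits the precision of every value below.

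Across the 248 miRNAs detected on all arrays, log2 levels correlated at r = 0.968 between the microglia replicates, 0.988 between the colon replicates and 0.963 between the liver replicates (across miRNAs, which are not independent replicates). Microglia correlated with the other populations at 0.784 to 0.872, and colon with liver macrophages at 0.936 to 0.946. Liver replicates differed by a median of 0.57 log2 units, against 0.26 for microglia and 0.23 for colon macrophages. miR-142-3p, which is expressed across blood cell lineages, was detected on every array, with levels of 12.08 and 12.31 on the microglia arrays, 11.89 and 12.30 on the colon arrays and 11.24 and 12.04 on the liver arrays.

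The first comparison asked which miRNAs set microglia apart from colon macrophages, which are continuously renewed from blood monocytes. miR-455-3p, encoded within the span of the collagen gene Col27a1, showed the largest rise among miRNAs measured in both groups, 9.16 ± 0.14 in microglia against 3.32 ± 0.45 in colon macrophages, a 57.1-fold difference (log2 change 5.84, SE 0.31, adjusted p = 0.000726, n = 2). Its partner arm miR-455-5p (6.19 ± 0.18) was not detected in colon macrophages and was at least 21.3-fold higher in microglia. miR-342-5p and miR-342-3p, from the Evl gene and expressed in myeloid cells, rose by 3.02 and 2.42 log2 units, and miR-99a-5p rose by 2.49 (adjusted p = 0.0033). In the other direction miR-223-3p, a myeloid miRNA that restrains granulocyte production, fell by 4.38 log2 units from 12.75 ± 0.11 in colon macrophages to 8.37 ± 0.14 in microglia (adjusted p = 0.00177). miR-511-3p, which lies in the mannose receptor gene Mrc1, stood at 9.11 ± 0.37 in colon macrophages, was not detected in microglia and was at least 147-fold lower there (adjusted p = 0.000726).

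The miR-181 family, known from lymphocyte development, stood among the clearest rises: miR-181a-5p rose by 2.72 and miR-181b-5p by 2.66 log2 units, and miR-181a-1-3p was at least 10.5-fold higher. Also higher in microglia were miR-467a-3p (log2 change 2.46) from the Sfmbt2 cluster, miR-100-5p (2.28) and miR-3106-5p, at least 16.1-fold, whose microglia replicates lay far apart (5.78 ± 1.63). miR-122-5p, the main miRNA of hepatocytes, was at 7.71 ± 0.57 in microglia and not detected in colon macrophages, at least 61.1-fold higher (adjusted p = 0.00108). Lower in microglia were miR-3472 (log2 change -3.75), miR-714 (-3.71), miR-494-3p (-3.32), miR-5105 (-3.29), miR-370-3p (-3.21) and miR-497-5p (-2.91), with adjusted p from 0.00226 to 0.0233. For miR-714 and miR-5105 no RefSeq miRNA gene was matched. miR-143-3p, a smooth muscle miRNA, was at least 30.5-fold lower in microglia, miR-468-3p at least 18.4-fold and miR-6392-3p at least 18.0-fold. miR-200c-3p, an epithelial miRNA, fell by 3.76 log2 units (adjusted p = 0.0477), with microglia replicates at 6.30 and 2.85 and colon replicates at 8.57 and 8.10.

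In all, 175 of 379 tested miRNAs differed between microglia and colon macrophages in limma's test, 67 higher and 108 lower in microglia, of which 17 higher ones were not detected in colon macrophages and 44 lower ones were not detected in microglia. For those the undetected group entered the test with an SD of 0 set by the floor. The arrays of the groups did not overlap for 85.2% of tested miRNAs, where 2 against 2 values drawn alike without selection would give 33.3%. That share is not a chance level here. The filter asks for detection on both arrays of a group, so miRNAs undetected in the other group mostly separate by construction. The median change of all tested miRNAs was -0.43 log2 units, and list medians below are given relative to it. The split moved with the scaling: it was 112 higher and 69 lower with median scaling (median change -0.05), 103 and 62 with quantile normalization (0.02), and 95 and 65 in the authors' value table (-0.02). It was 29 and 108 with no scaling (-0.76) and 25 and 105 with scaling on spike-in controls (-0.85), the latter chosen after the data were seen. Only 27 miRNAs passed without the detection filter, and 111 passed when only miRNAs detected on all arrays were tested. The count was 75 without microglia replicate 2, 53 without colon replicate 1 and 80 without colon replicate 2. Without microglia replicate 1 it was 134, with 72 higher and 62 lower.

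All 4 tested members of the list of miRNAs that earlier studies reported in microglia rose against colon macrophages, also 4 when adjusted over the list alone: miR-99a-5p, miR-342-3p, miR-342-5p and miR-125b-5p (log2 change 1.93). The list's median lay 2.88 log2 units above that of all miRNAs (adjusted p = 0.0106 at the preset correlation, adjusted p = 0.835 with an estimated correlation). Of the miR-181 list 3 of 4 members rose (also 3 adjusted over the list alone), with a median 2.81 above that of all miRNAs (adjusted p = 0.0183, and adjusted p = 0.835 with an estimated correlation). The miR-17-92 cluster and its paralogs, which drive proliferation in many tissues, had 5 of 12 members higher, 7 adjusted over the list alone, among them miR-92a-3p (1.57) and miR-20a-5p (1.19). Their median lay 1.39 above that of all miRNAs (adjusted p = 0.00326, and adjusted p = 0.835 with an estimated correlation). The number of members called depended on the scaling: over 5 other scalings (median, quantile, none, the authors' values and spike-in controls) 0 to 12 of the 12 were higher, with 12 after median scaling and 0 in limma's test with no scaling or on spike-in controls (1 member at an unadjusted p under the threshold in each). A sixth scaling, the 75th percentile over all miRNAs, is left out of these ranges because it scales microglia replicate 1 by a placeholder. Under it limma called 0 members of any list, and 11 of the 12 passed at an unadjusted p under the threshold. In the miR-29 list, whose members repress collagen and other matrix transcripts, 3 of 5 rose (3 adjusted over the list alone), including miR-29a-3p (1.18). Its median lay 1.61 above that of all miRNAs (adjusted p = 0.0437, and adjusted p = 0.835 with an estimated correlation). All 5 tested members of the smooth muscle and fibroblast list fell (5 adjusted over the list alone), with miR-199a-3p, miR-199a-5p, miR-199b-5p and miR-214-3p beside miR-143-3p. Their median lay -4.15 from that of all miRNAs, the unshifted median being -4.58 with undetected members at their bounds as well (adjusted p = 0.0223, and adjusted p = 0.835 with an estimated correlation). Over the same scalings 3 to 4 members of the microglia list, 2 to 4 of the miR-181 list and 1 to 4 of the miR-29 list were higher, and 3 to 5 of the smooth muscle list lower. With each array left out in turn, the members higher numbered 2 to 4 in the microglia list, 2 to 3 in the miR-181 list, 0 to 10 in the miR-17-92 list and 0 to 5 in the miR-29 list, and 2 to 4 smooth muscle members were lower. In limma's test 0 members of the miR-17-92 and miR-29 lists were higher without microglia replicate 2 or either colon array (at least 5 and 1 at an unadjusted p under the threshold). Without either liver array 10 and 5 were higher.

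Other lists did not pass the list test against colon macrophages at the preset correlation, though single members did. Of 7 tested neuronal miRNAs 4 were higher and 2 lower (6 adjusted over the list alone, list adjusted p = 0.227). Among them miR-124-3p was at 3.97 ± 0.16 in microglia and detected on 1 colon array, miR-9-5p was at 3.40 and 3.59 on the microglia arrays and not detected on the colon arrays, and miR-132-3p was lower (log2 change -4.00). The lymphocyte list had 3 of 4 members higher (3 adjusted over the list alone, adjusted p = 0.12), which were miR-150-3p and the miR-181 members it shares with the miR-181 list. Of the miR-30 list 4 of 7 were higher (4 adjusted over the list alone, adjusted p = 0.0581), of let-7 2 of 10 (1 adjusted over the list alone, adjusted p = 0.0939) and of oligodendrocyte markers 1 of 4, miR-219-5p (1 adjusted over the list alone, adjusted p = 0.465). In the miR-15/16 list 3 of 5 were higher and 1 lower (4 adjusted over the list alone, adjusted p = 0.465), and in the miR-99, miR-100, miR-125 and miR-10 list 3 of 8 were higher and 3 lower (6 adjusted over the list alone, adjusted p = 0.79). Of miRNAs that respond to inflammation 3 of 6 were lower, miR-132-3p, miR-221-3p and miR-222-3p (3 adjusted over the list alone, adjusted p = 0.4). From the Dlk1-Dio3 cluster 2 of 5 were lower, miR-370-3p and miR-494-3p (2 adjusted over the list alone, adjusted p = 0.46). In the myeloid list 1 of 9, miR-223-3p, was lower (1 adjusted over the list alone, adjusted p = 0.906). Over 5 other scalings the members higher numbered 0 to 5 in the miR-30 list, 0 to 8 in let-7, 0 to 3 in the miR-15/16 list and 0 to 2 among oligodendrocyte markers. They numbered 2 to 4 among neuronal markers and 2 to 3 in each of the lymphocyte and miR-99, miR-100, miR-125 and miR-10 lists, and up to 1 in the inflammation and myeloid lists. Members lower numbered 0 to 2 among neuronal markers, 2 to 3 in the inflammation list and 1 to 2 in the myeloid list. Leaving out each array in turn gave 0 to 3 higher in the miR-30 list, 0 to 1 in let-7, 0 to 3 in the miR-15/16 list, 0 to 2 among oligodendrocyte markers, 2 to 4 among neuronal markers, 2 to 3 in the lymphocyte list and 1 to 3 in the miR-99, miR-100, miR-125 and miR-10 list. It gave 0 to 2 lower among neuronal markers and in the miR-15/16 list, and 1 to 4 in the miR-99, miR-100, miR-125 and miR-10 list. Further members lower numbered 1 to 3 in the inflammation and Dlk1-Dio3 lists, 1 to 2 in the myeloid list and up to 1 in the let-7 and miR-30 lists. In each of these ranges that starts at 0 in limma's test, at least 1 member passed at an unadjusted p under the threshold. In those given as up to a number some fits had 0 at an unadjusted p under the threshold as well. Without microglia replicate 1 the miR-30 list had 1 of 8 higher, let-7 had 1 higher, the neuronal list 2 higher and 1 lower, and the oligodendrocyte list 0 higher in limma's test (1 at an unadjusted p under the threshold). The medians of the myeloid and miR-99, miR-100, miR-125 and miR-10 lists had the opposite sign to the test or the mean, and both changed sign under at least 1 other scaling.

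Markers of other cell types differed between arrays of the same group as well as between groups. On both colon arrays 12 epithelial miRNAs were detected, with miR-200b-3p at 10.34 and 9.86, and 9 of them were higher by over 1 log2 unit on microglia replicate 1 than on replicate 2: miR-200b-3p was at 7.94 on replicate 1 and not detected on replicate 2. miR-203-3p was at 5.62 and 5.58 on the microglia arrays. Against colon macrophages 4 of 12 epithelial members were lower in microglia and 1, miR-203-3p, was higher (12 adjusted over the list alone, adjusted p = 0.124), and without microglia replicate 1 the list passed, with 9 lower (adjusted p = 0.000475 at the preset correlation, and adjusted p = 0.89 with an estimated correlation). Epithelial members lower numbered 1 to 6 over 5 other scalings and 1 to 9 with each array left out in turn. miR-203-3p was not called with no scaling, on spike-in controls or without either microglia or either liver array. The endothelial list had 2 of 5 members higher and 3 lower (5 adjusted over the list alone, adjusted p = 0.968) and the hepatocyte list 1 of 4 higher, miR-122-5p (4 adjusted over the list alone, adjusted p = 0.968). For the endothelial list the median was negative and the test pointed up. Endothelial members numbered 0 to 2 higher and 0 to 3 lower over 5 other scalings, and 0 to 2 higher and 0 to 2 lower with each array left out in turn (in limma's test at least 1 in each direction at an unadjusted p under the threshold). Hepatocyte members lower numbered 2 without microglia replicate 1, where the median moved from -3.33 to -4.70, and 1 was lower without colon replicate 2 or either liver array. Of the erythrocyte and platelet list miR-451a alone was tested, at 9.46 and 6.93 on the microglia arrays, 5.88 and 5.68 on the colon arrays and 7.43 and 7.30 on the liver arrays, and it passed in no comparison. Without microglia replicate 1 it was higher in microglia than in colon macrophages (log2 change 1.16 against 2.42 with that array) and lower in colon than in liver macrophages (-1.60 against -1.59). Without microglia replicate 2 the list had 2 members tested, and both were higher in microglia than in each other population. Endothelial miR-126-3p and fibroblast miR-199a-3p were also detected on microglia replicate 1 (5.15 and 5.00) and not on replicate 2.

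**Figure D1:**
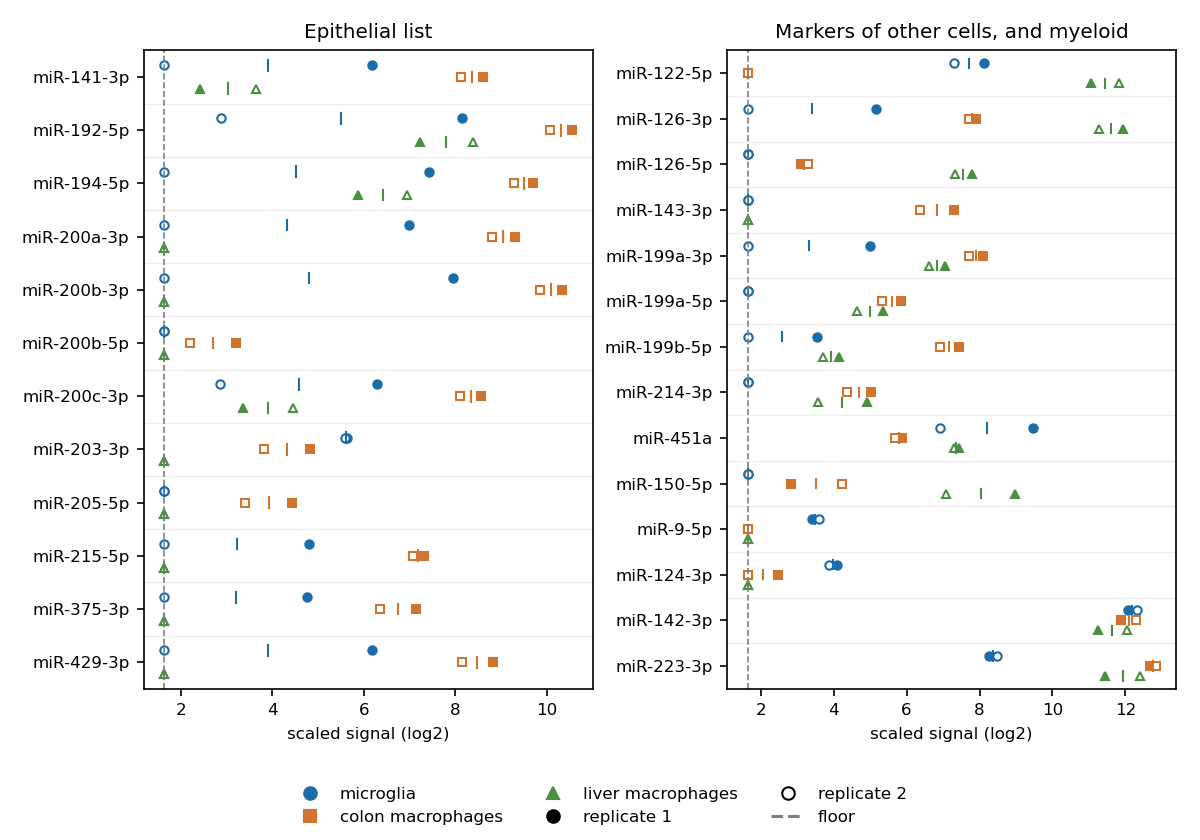
Scaled signal (log2, horizontal axis) of the epithelial list (left) and of markers of other cells with 2 myeloid miRNAs (right), 1 point per array, filled for replicate 1 and open for replicate 2, with a vertical tick at each group's mean and a dashed line at the floor of 1.64, where values not detected lie. Epithelial miRNAs such as miR-200b-3p stand at 7.94 on microglia replicate 1 and at the floor on replicate 2, and miR-122-5p stands at 8.11 and 7.30 on the microglia arrays and at the floor on the colon arrays.

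The second comparison set microglia against liver macrophages, which like microglia are largely seeded before birth and maintain themselves in the adult. miR-455-3p again rose most among miRNAs measured in both groups, to 9.16 ± 0.14 from 3.30 ± 0.04 in liver macrophages (log2 change 5.86, SE 0.31, adjusted p = 0.000604, n = 2). miR-99a-5p and miR-125b-5p, members of a conserved cluster with let-7c, rose by 3.90 and 2.82 log2 units, from 6.84 ± 0.08 and 8.57 ± 0.28 in liver macrophages. miR-181a-5p rose by 3.51 and miR-181b-5p by 3.34. miR-126-5p, an endothelial miRNA of the Egfl7 gene, was at 7.56 ± 0.34 in liver macrophages, was not detected in microglia and was at least 50.1-fold lower there (adjusted p = 0.000604). miR-511-3p was at least 110-fold lower in microglia and miR-150-5p, a miRNA of mature lymphocytes, at least 69.6-fold (adjusted p = 0.000677 and 0.00277).

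Further rises against liver macrophages were those of miR-326-3p (log2 change 2.82), miR-744-5p (2.91) and miR-150-3p (3.32), the last resting on microglia replicates at 3.63 and 6.42. The liver means of miR-744-5p and miR-150-3p were 1.68 and 1.70, next to the floor of 1.64, so the size of these changes depends on the floor. Among miRNAs not detected in liver macrophages miR-455-5p was at least 26.5-fold higher in microglia, miR-3106-5p at least 20.0-fold, miR-203-3p at least 17.7-fold and miR-181a-1-3p at least 13.2-fold. Falls were measured for miR-370-3p (-4.43), miR-5105 (-3.88), miR-3472 (-3.74), miR-223-3p (-3.56), miR-6243 (-3.51), miR-3077-5p (-3.01) and miR-5121 (-2.97), with adjusted p from 0.000933 to 0.0178. No RefSeq miRNA gene was matched to miR-5105 or miR-6243. miR-6392-3p was at least 37.9-fold lower in microglia. miR-122-5p fell by 3.74 log2 units from 11.44 ± 0.54 in liver macrophages to 7.71 ± 0.57 (adjusted p = 0.00219).

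Of 382 miRNAs tested against liver macrophages 202 passed in limma's test, 81 higher and 121 lower in microglia, with 16 higher ones not detected in liver macrophages and 53 lower ones not detected in microglia. The groups' arrays did not overlap for 81.4% of tested miRNAs, a share that the filter on detection raises as above. The median change was -0.60 log2 units. The split was 124 higher and 108 lower with median scaling (median change -0.19), 111 and 93 with quantile normalization (-0.16), 107 and 99 in the authors' value table (-0.24), 36 and 126 with no scaling (-0.82) and 34 and 120 on spike-in controls (-0.87). The count was 52 without the detection filter and 117 without microglia replicate 2. Without microglia replicate 1 it was 163, with 81 higher and 82 lower.

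Against liver macrophages the list from earlier microglia studies again had 4 of 4 members higher (4 adjusted over the list alone), with a median 2.88 log2 units above that of all miRNAs. Its adjusted p was 0.0167 at the preset correlation (adjusted p = 0.835 with an estimated correlation). The miR-181 list had 3 of 4 higher (3 adjusted over the list alone), with a median 3.58 above that of all miRNAs (adjusted p = 0.0183, and adjusted p = 0.835 with an estimated correlation). In the miR-17-92 list 9 of 12 rose (9 adjusted over the list alone), with miR-20a-5p at a log2 change of 1.86 and miR-19b-3p at 1.42. The list's median lay 1.97 above that of all miRNAs (adjusted p = 0.00118, and adjusted p = 0.835 with an estimated correlation). The let-7 list, miRNAs of differentiated cells, had 3 of 10 higher (3 adjusted over the list alone), let-7i-5p (1.99), let-7d-3p (1.48) and let-7c-5p (1.19), with a median 1.19 above that of all miRNAs (adjusted p = 0.0223, and adjusted p = 0.835 with an estimated correlation). Over 5 other scalings 2 to 12 members of the miR-17-92 list, 1 to 9 of let-7, 2 to 4 of the microglia list and 3 to 4 of the miR-181 list were higher. With each array left out in turn these numbers were 5 to 9, 1 to 3, 2 to 4 and 2 to 3.

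Of the list calls against colon and liver macrophages, only that of the miR-17-92 list in both comparisons held in every alternative in which the list test was run at the preset correlation. That test was not run with median scaling, with no scaling or on the authors' values. Removing microglia replicate 1 ended the calls of the microglia list (adjusted p = 0.0702 in both comparisons), of miR-181 (0.122 in both), of miR-29 (0.196) and of let-7 (0.0545). The unshifted medians without that replicate were 2.70 and 2.52 for the microglia list against colon and liver macrophages (2.45 and 2.28 with it), 2.54 and 3.16 for miR-181 (2.38 and 2.97), 1.22 for miR-29 (1.18) and 0.81 for let-7 (0.59). Quantile normalization ended the calls of the same lists, with adjusted p from 0.0507 to 0.117. The medians were then 2.51 and 2.47 for the microglia list, 2.87 and 3.52 for miR-181, 1.48 for miR-29 and 0.84 for let-7. The miR-29 call was also lost with a floor of 1 (0.0776, median 1.18), among miRNAs detected on all arrays (0.262, median 0.82) and without microglia replicate 2 (0.0722, median 1.17). It was lost too without colon replicate 1 (0.071, median 1.20) or colon replicate 2 (0.0522, median 1.13). The smooth muscle call against colon macrophages was lost without liver replicate 1 (0.0757, median -4.51) or 2 (0.0603, median -4.50). The miR-181 call against liver macrophages was lost without liver replicate 2 (0.0603, median 2.64). The let-7 call was lost on spike-in controls (0.0749, median 0.17) and among miRNAs detected on all arrays (0.108, median 0.59). With the 75th percentile over all miRNAs those of miR-29 (0.151), let-7 (0.0863) and miR-181 against colon macrophages (0.0522) were lost. Too few smooth muscle members were detected on all arrays for a test.

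The remaining lists did not pass against liver macrophages. Neuronal markers had 3 of 7 higher, miR-124-3p, miR-9-5p and miR-9-3p, and 2 lower, miR-7a-5p and miR-132-3p (5 adjusted over the list alone, adjusted p = 0.351). The lymphocyte list had 3 of 4 higher and 1 lower (4 adjusted over the list alone, adjusted p = 0.187), with miR-150-5p on the liver arrays at 8.97 and 7.09. Of the miRNAs that respond to inflammation miR-146a-5p and miR-146b-5p, which dampen Toll-like receptor signalling, were higher (log2 change 1.31 and 2.77) and 3 of 6 were lower (6 adjusted over the list alone, adjusted p = 0.79). The smooth muscle and fibroblast list had 3 of 4 lower (3 adjusted over the list alone, adjusted p = 0.206), the Dlk1-Dio3 list 3 of 6 lower (3 adjusted over the list alone, adjusted p = 0.227) and the endothelial list 1 of 5 higher and 2 lower, miR-126-3p and miR-126-5p (3 adjusted over the list alone, adjusted p = 0.765). The miR-29 list had 3 of 5 higher (3 adjusted over the list alone, adjusted p = 0.158), the miR-30 list 3 of 8 higher and 1 lower (4 adjusted over the list alone, adjusted p = 0.442), the miR-15/16 list 3 of 5 higher and 2 lower (5 adjusted over the list alone, adjusted p = 0.465) and the miR-99, miR-100, miR-125 and miR-10 list 4 of 9 higher and 3 lower (8 adjusted over the list alone, adjusted p = 0.458). In the myeloid list 2 of 9 were lower, miR-223-3p and miR-23a-5p (1 adjusted over the list alone, adjusted p = 0.633), the mean being negative while the median and the test were positive. Oligodendrocyte markers had 1 of 4 higher (0 adjusted over the list alone and 1 at an unadjusted p under the threshold in limma's test, adjusted p = 0.605), hepatocyte markers 1 of 4 lower, miR-122-5p (1 adjusted over the list alone, adjusted p = 0.4), and epithelial markers 1 of 5 higher, miR-203-3p (1 adjusted over the list alone, adjusted p = 0.465). Over 5 other scalings the members higher numbered 0 to 4 in the miR-30 list, 0 to 3 in the miR-15/16 list, 1 to 3 in the miR-29 list, 2 to 5 in the miR-99, miR-100, miR-125 and miR-10 list and 0 to 2 in each of the oligodendrocyte and endothelial lists. They numbered 1 to 2 in the inflammation list, 2 to 3 in the lymphocyte list and up to 4 in the myeloid list. Members lower numbered 1 to 3 in the smooth muscle list, 2 to 3 in the inflammation list, 1 to 2 in the neuronal, myeloid and miR-15/16 lists and up to 1 in the miR-30 list. In limma's test on spike-in controls 0 were higher in the miR-30, oligodendrocyte, endothelial and miR-15/16 lists (0, 0, 1 and 2 at an unadjusted p under the threshold). With no scaling and on spike-in controls the medians turned negative in the myeloid list (-0.03 and -0.07) and the oligodendrocyte list (-0.21 and -0.26).

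Leaving out each array in turn against liver macrophages gave 0 to 2 higher in the miR-30, oligodendrocyte and endothelial lists, 0 to 3 in the miR-15/16 list, 0 to 4 in the miR-29 list and 2 to 5 in the miR-99, miR-100, miR-125 and miR-10 list. It gave 2 to 4 higher among neuronal markers, 2 to 3 in the lymphocyte list, 1 to 2 in the inflammation list, 1 to 6 among epithelial markers and up to 2 in the myeloid list. Members lower numbered 1 to 3 in the smooth muscle, Dlk1-Dio3, hepatocyte and endothelial lists, and 1 to 2 in the miR-30, miR-15/16, myeloid, neuronal and inflammation lists. They numbered 0 to 1 in the lymphocyte list, up to 2 among epithelial and oligodendrocyte markers and up to 1 in the miR-29 list. In the ranges that start at 0 in limma's test at least 1 member passed at an unadjusted p under the threshold, except among oligodendrocyte markers higher without microglia replicate 1 (0 at an unadjusted p under the threshold). In those given as up to a number some fits had 0 at an unadjusted p under the threshold as well. Without that array the hepatocyte list had 3 of 4 lower and its median moved from -2.09 to -4.51, 2 epithelial markers were lower, and the members higher were 1 in each of the miR-29 and miR-30 lists and 2 in the miR-99, miR-100, miR-125 and miR-10 list. Without microglia replicate 2, 6 epithelial markers were higher.

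The study's main question concerned miRNAs higher in microglia than in both other populations, of which 58 were found. Among the 58 are miR-124-3p, miR-9-5p and miR-9-3p of the neuronal list, miR-219-5p of the oligodendrocyte list and miR-203-3p of the epithelial list. Whether microglia or other cells gave these was not tested. By the size of the smaller change miR-455-3p came first, followed by miR-455-5p, miR-3106-5p and miR-181a-1-3p, and miR-181a-5p (9.86 ± 0.18 in microglia) and miR-181b-5p (7.85 ± 0.34) were also among the 12 named. miR-190a-5p, from the Tln2 gene, was at 4.76 ± 0.02 in microglia and detected in neither other group, at least 7.93-fold above colon and 9.88-fold above liver macrophages. miR-467e-5p (4.59 ± 0.12) and miR-466b-3p (4.35 ± 0.20), both within the span of Sfmbt2, were at least 7.02- and 5.94-fold above colon macrophages and at least 8.75- and 7.41-fold above liver macrophages. miR-744-5p (4.59 ± 0.28) was at least 7.02-fold above colon macrophages and rose by 2.91 log2 units against liver macrophages, where it was detected near the floor. miR-3106-5p, miR-3070a-3p (4.96 ± 1.61) and miR-150-3p (5.02 ± 1.97) had the widest spread between microglia replicates among the 12.

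Lower in microglia than in both other populations were 72 miRNAs. Among those detected on all 6 arrays, the ones whose smaller change was largest were miR-3472 (log2 change -3.75 against colon and -3.74 against liver macrophages), miR-223-3p (-4.38 and -3.56), miR-5105 (-3.29 and -3.88), miR-370-3p (-3.21 and -4.43), miR-494-3p (-3.32 and -2.95) and miR-714 (-3.71 and -2.82). Of these miR-5105 and miR-714 had no RefSeq miRNA gene of that name. Endothelial miR-126-3p and miR-126-5p and fibroblast miR-199a-3p, miR-199a-5p and miR-214-3p were also among the 72. miR-223-3p stood on the 2 microglia arrays at 8.27 and 8.47, and on the other 4 arrays between 11.45 and 12.83. Calls in opposite directions were made for miR-122-5p, higher in microglia than in colon and lower than in liver macrophages, and for miR-34a-5p, lower than in colon and higher than in liver macrophages.

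Among the 347 miRNAs tested in both comparisons, independent lists of 67 and 81 higher calls would share 15.6, and lists of 90 and 100 lower calls would share 25.9, against the 58 and 72 observed. In 100 simulated data sets with no group effect limma made a mean of 0.055 calls per comparison, so that the 0 calls shared there bear little on the overlap. At an unadjusted p under the threshold the simulated comparisons shared a mean of 2.02 higher and 1.84 lower miRNAs, where independent lists would share 0.171 and 0.156, and the measured ones shared 70 and 91. Both comparisons use the same microglia arrays, which are too few to split, so part of the excess may come from the shared arrays. The number higher in both was 101 with median scaling, 21 with no scaling and 18 on spike-in controls, and the number lower in both was 43 with quantile normalization. Without the detection filter 14 were higher and 9 lower in both. Higher and lower in both were 25 and 36 without microglia replicate 2, 18 and 23 without colon replicate 1 and 21 and 37 without colon replicate 2. Without microglia replicate 1, the array with epithelial miRNAs, some of the 58 and of the 72 were no longer called and others were newly called. Counts with an array left out, here and in the other comparisons, therefore do not say that the same miRNAs were called.

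**Figure D2:**
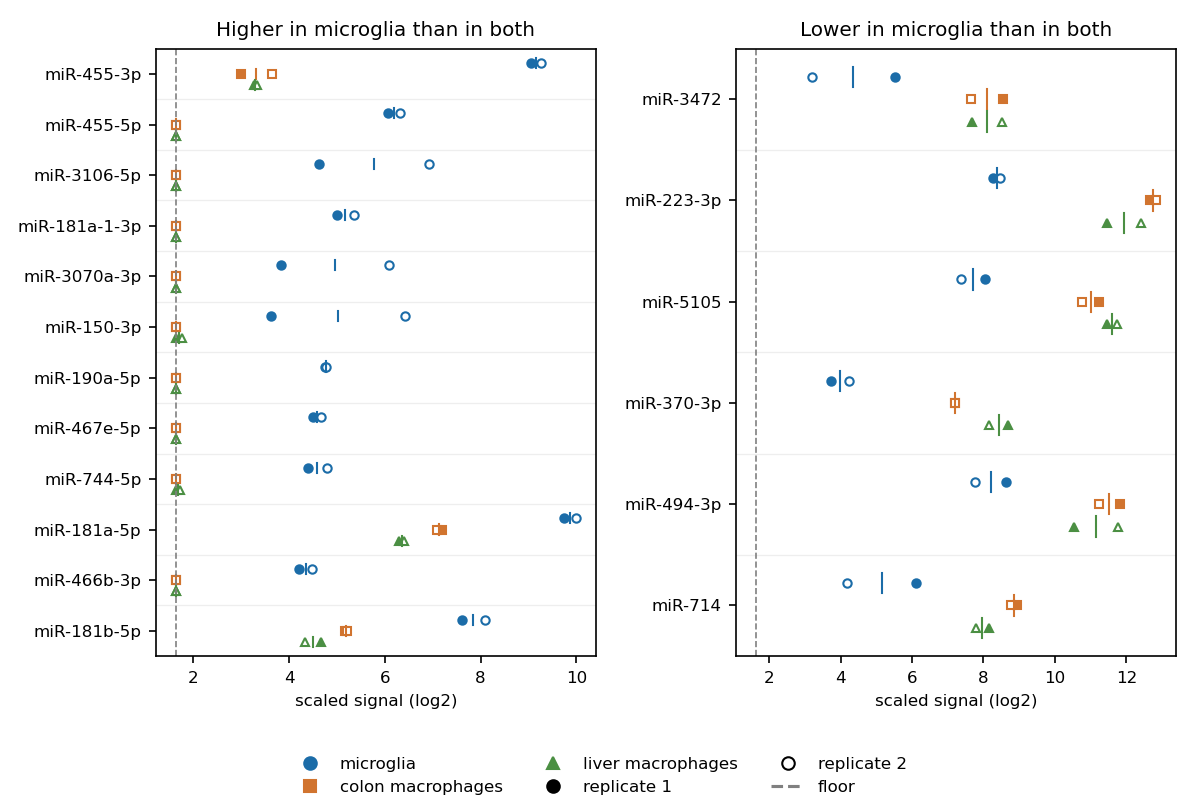
Scaled signal (log2, horizontal axis) of the 12 miRNAs named as higher (left) and the 6 named as lower (right) in microglia than in both other populations, 1 point per array, filled for replicate 1 and open for replicate 2, with a vertical tick at each group's mean and a dashed line at the floor of 1.64. miR-455-3p averages 9.16 in microglia against 3.32 and 3.30 in colon and liver macrophages, and miR-223-3p averages 8.37 against 12.75 and 11.93.

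**Figure D3:**
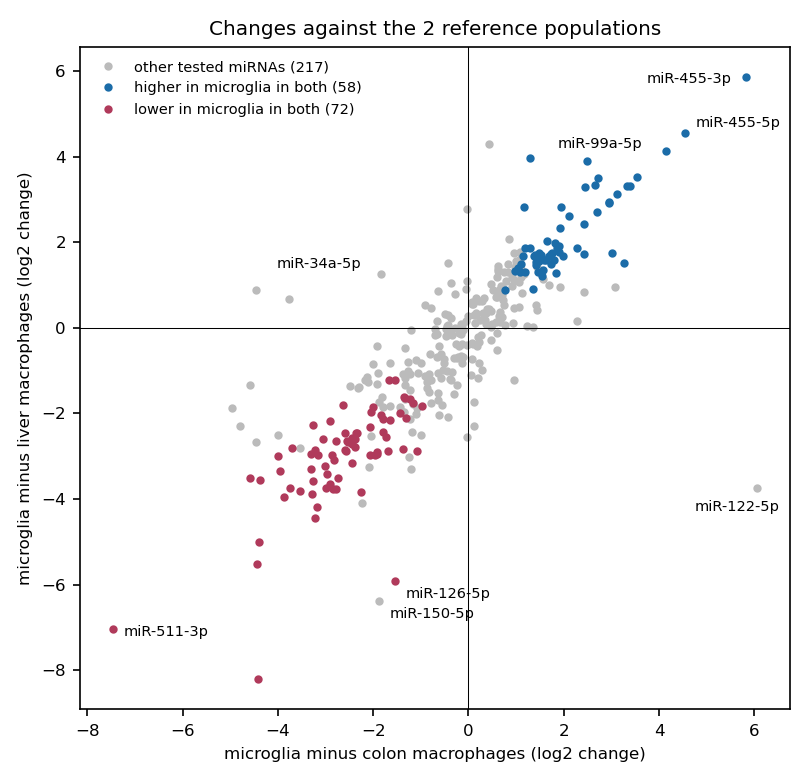
Log2 change of each of the 347 miRNAs tested in both comparisons, microglia minus colon macrophages (horizontal axis) against microglia minus liver macrophages (vertical axis), 1 point per miRNA, with the 58 higher in both in blue and the 72 lower in both in red. miR-455-3p lies at 5.84 and 5.86 and miR-511-3p at -7.47 and -7.05 with undetected values at the floor, while miR-122-5p lies off the diagonal at 6.07 and -3.74.

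The third comparison set the reference populations against each other. miR-122-5p was at 11.44 ± 0.54 in liver macrophages and not detected in colon macrophages, at least 814-fold lower there (adjusted p = 0.000696, n = 2). Colon macrophages had higher miR-34a-5p, a target of the p53 pathway (10.07 ± 0.25 against 6.97 ± 0.57, log2 change 3.09, SE 0.39, adjusted p = 0.0141), miR-146b-5p (2.79) and miR-199b-5p (3.25). miR-429-3p, miR-215-5p and miR-375-3p, miRNAs of intestinal and other epithelia, were not detected in liver macrophages and were at least 130-, 53.0- and 39.0-fold higher in colon macrophages, and miR-143-3p was at least 41.7-fold higher. Liver macrophages had higher miR-126-5p (7.56 ± 0.34 against 3.19 ± 0.14, log2 change -4.37 for colon minus liver, adjusted p = 0.00203) and miR-150-5p (8.03 ± 1.33 against 3.52 ± 0.98, log2 change -4.51). These are levels of the sorted samples. Whether the macrophages themselves or other cells gave the hepatocyte, epithelial, smooth muscle, endothelial and lymphocyte miRNAs was not tested.

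Smaller rises in colon macrophages were those of miR-326-3p (log2 change 1.66), miR-125a-5p (1.49), miR-10b-5p (1.49), miR-27b-3p (1.43) and miR-99a-5p (1.42), with adjusted p from 0.0315 to 0.0464. Lower in colon macrophages were miR-151-5p (-2.53), miR-546 (-2.08), miR-7a-5p (-1.79), miR-878-3p (-1.65), miR-680 (-1.42) and miR-292-5p (-1.37). miR-6236, miR-3102-3p and miR-490-5p were not detected in colon macrophages and were at least 6.55-, 6.50- and 6.35-fold lower there.

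Of 396 tested miRNAs 40 differed between colon and liver macrophages in limma's test, 21 higher and 19 lower in colon macrophages, with 12 and 8 of them not detected in the dimmer group and a median change of -0.04 log2 units over all tested. The arrays did not overlap for 59.6% of tested miRNAs, again a share raised by the filter on detection. The split was 20 higher and 31 lower with median scaling. The count was 26 with no scaling, 24 on spike-in controls, 19 among miRNAs detected on all arrays and 7 without the detection filter. It was 19 without colon replicate 1, 109 without liver replicate 1 and 63 without liver replicate 2, and 33 without microglia replicate 1, which enters through the shared estimate of the spread.

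Between colon and liver macrophages the epithelial list had 5 of 12 members higher and 10 adjusted over the list alone, all 12 changes being positive. Its median lay 4.81 log2 units above that of all miRNAs (4.77 unshifted and 4.86 with undetected members at their bounds), with adjusted p = 2.1e-06 at the preset correlation and adjusted p = 0.835 with an estimated correlation. Of the smooth muscle and fibroblast list 2 of 5 were higher, miR-143-3p and miR-199b-5p (2 adjusted over the list alone), with a median 1.11 above that of all miRNAs (adjusted p = 0.0223, and adjusted p = 0.835 with an estimated correlation). The epithelial members higher ranged from 2 to 5 over 5 other scalings, in each of which at least 9 passed at an unadjusted p under the threshold in limma's test. They ranged from 0 to 7 with each array left out in turn, with 0 in limma's test without liver replicate 1 or 2 (2 and 3 at an unadjusted p under the threshold), though the list test at the preset correlation passed in each. Smooth muscle members higher numbered 1 to 2 over the scalings and 1 to 3 over the arrays left out. The smooth muscle call, with an unshifted median of 1.08, ended with quantile normalization (adjusted p = 0.0536, median 1.04), with a floor of 1 (0.0603, median 1.08) and without colon replicate 1 (0.071, median 0.89) or liver replicate 2 (0.34, median 0.85). No other list passed. The endothelial list had 1 of 5 lower in colon macrophages, miR-126-5p (2 adjusted over the list alone, adjusted p = 0.158), the hepatocyte list 1 of 4 lower, miR-122-5p (1 adjusted over the list alone, adjusted p = 0.79), and the lymphocyte list 1 of 4 lower, miR-150-5p (2 adjusted over the list alone, adjusted p = 0.811). For the hepatocyte list the median was positive and the mean and test negative, and for the lymphocyte list the mean alone was negative. The lower call in the lymphocyte list was lost in limma's test with quantile normalization, on the authors' values, where the median was -0.21, and on leaving out any array but liver replicate 2 (0 called and 1 at an unadjusted p under the threshold in each). In that list 1 member was higher without microglia replicate 1. Members lower with each array left out in turn numbered 1 to 2 in the endothelial list and 1 to 3 in the hepatocyte list.

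In the other lists few members separated colon from liver macrophages. Of the miR-99, miR-100, miR-125 and miR-10 list 3 of 9 were higher and miR-99b-3p was lower (5 adjusted over the list alone, adjusted p = 0.278), and of miRNAs that respond to inflammation 1 of 6, miR-146b-5p, was higher (1 adjusted over the list alone, adjusted p = 0.283). miR-99a-5p was the only 1 of 4 from the microglia list to pass (2 adjusted over the list alone, adjusted p = 0.79), miR-7a-5p the only 1 of 4 neuronal markers (1 adjusted over the list alone, adjusted p = 0.52) and miR-30b-3p the only 1 of 8 from the miR-30 list (1 adjusted over the list alone, adjusted p = 0.184). By limma's test over all miRNAs 0 members passed in each of the oligodendrocyte (list adjusted p = 0.765, 2 members at an unadjusted p under the threshold), let-7 (0.367, 1 member), miR-29 (0.79, 1 member), miR-181 (0.204, 1 member) and Dlk1-Dio3 (0.292, 1 member) lists, and only the miR-29 list had 1 past the threshold adjusted over the list alone. In the myeloid (adjusted p = 0.265), miR-17-92 (0.206) and miR-15/16 (0.79) lists 0 members passed limma's test even at an unadjusted p under the threshold. In the miR-29 list the median was positive and the mean and test negative. Members higher in the miR-99, miR-100, miR-125 and miR-10 list numbered 0 to 3 over 5 other scalings and 0 to 2 with each array left out in turn. In limma's test 0 were higher with no scaling, on spike-in controls and without either microglia array (at least 3 at an unadjusted p under the threshold). Over the arrays left out limma called 0 members of the microglia list in every case, 0 to 2 higher in the inflammation list and 0 to 2 lower in the neuronal and miR-30 lists (at least 1 at an unadjusted p under the threshold in each). Lists with 0 calls gained up to 2 in the myeloid list and up to 1 in the others.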

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

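The alternatives were chosen before the data were examined, except scaling on spike-in controls, which was added after they were seen. Signal over background limits what can be said of the 765 miRNAs detected on no array and of changes against groups at the floor. With the 75th percentile taken over all 1247 miRNAs, the percentile of microglia replicate 1 falls on the placeholder for undetected miRNAs, so that array is scaled by a placeholder. By this construction limma called 0 miRNAs in each comparison and 0 higher or lower in both (at an unadjusted p under the threshold 120, 131 and 8 for microglia against colon, microglia against liver and colon against liver macrophages). It also turned 16 log2 changes of named miRNAs positive: against colon macrophages those of miR-200c-3p (0.0957), miR-3472 (0.107), miR-714 (0.15), miR-494-3p (0.54), miR-5105 (0.57), miR-370-3p (0.65) and miR-497-5p (0.95), and against liver macrophages those of miR-5105 (0.12), miR-3472 (0.26), miR-122-5p (0.27), miR-223-3p (0.45), miR-6243 (0.50), miR-3077-5p (0.996), miR-5121 (1.03), miR-494-3p (1.05) and miR-714 (1.19). No other alternative turned the direction of a named miRNA.

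Counts outside 1.5 times the reported one were the following, and the cause was not tested unless given. Median scaling gave 101 higher in both, quantile normalization 43 lower in both, and no scaling 26 for colon against liver macrophages and 21 higher in both. Scaling on spike-in controls gave 24 for colon against liver macrophages and 18 higher in both. Testing only miRNAs detected on all arrays, which removes miRNAs by construction, gave 111 for microglia against colon and 19 for colon against liver macrophages. Without a detection filter, which adds undetected miRNAs to the adjustment and to the shared spread, the counts were 27 and 52 for microglia against colon and liver macrophages, 7 for colon against liver macrophages, 14 higher in both and 9 lower in both. With the replicate number as a block colon against liver macrophages gave 24, and the other counts stayed within 1.5 times (161, 191, 46 and 70). Replicate deviations correlated across miRNAs at 0.214, 0.0715 and -0.0922 between groups, and the labels do not say that the numbers pair samples. Leaving out each array in turn, with the lone sample assumed to vary like the other groups, gave 53 to 203 for microglia against colon, 117 to 221 for microglia against liver, 19 to 109 for colon against liver macrophages, 18 to 67 higher in both and 23 to 95 lower in both. The removals that moved a count by over 1.5 times were those of microglia replicate 2 and both colon replicates for microglia against colon macrophages and for the miRNAs higher or lower in both, microglia replicate 2 for microglia against liver macrophages, and colon replicate 1 and both liver replicates for colon against liver macrophages. Of 84 changes of named miRNAs, 77 kept direction and threshold with median scaling, 75 with quantile normalization, 74 with no scaling, the authors' value table or a floor of 1, 72 on spike-in controls, 73 with the replicate block, 35 without a detection filter and 50 to 71 with an array left out. Of 11 list calls, 0 held with an estimated correlation, 4 with quantile normalization, 6 among miRNAs detected on all arrays, 11 with the replicate block and 5 to 10 with an array left out. A background correction and a slide or scan block were not run for want of the columns they need.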

Other observations

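The correlations of arms and the tests of explanations in this part were chosen only after the results were seen, and the miRNAs named here were picked after their values were seen. Of 6 tested miRNAs from neighbouring genes (RefSeq, GRCm38.p6), 3 were higher in microglia than in both other populations. miR-322-5p, the mouse form of miR-424 and a brake on the cell cycle, was at 9.78 ± 0.12 in microglia and rose by 1.91 log2 units against colon and 1.78 against liver macrophages (limma adjusted p = 0.011 and 0.00933, n = 2). miR-450a-5p rose by 1.52 against liver macrophages and was not detected in colon macrophages, and miR-542-3p (3.55 ± 0.79) was detected in microglia alone (adjusted p = 0.0223 and 0.017). miR-503-5p rose by 1.93 against colon macrophages, and its log2 change of 0.96 against liver macrophages did not pass (adjusted p = 0.143). miR-542-5p passed in neither comparison (adjusted p = 0.104 and 0.2), and miR-450a-2-3p was not detected in microglia, lower there than in liver macrophages (3.66 ± 0.57, adjusted p = 0.0172) and not past the threshold against colon macrophages (adjusted p = 0.0927). No set test was run on these neighbours. miR-21a-5p, a miRNA of activated and proliferating cells, was at 11.86 ± 0.08 in microglia and fell by 2.36 against colon (14.22 ± 0.03) and 2.47 against liver macrophages (14.33 ± 1.17). Colon macrophages alone carried miR-196a-5p (5.58 ± 0.27), which lies in the Hox clusters and was detected in neither other group, and miR-196b-5p (5.92 ± 0.40) was higher there than in microglia, where 1 array detected it, and was not detected in liver macrophages. miR-145a-5p and miR-1a-3p, muscle miRNAs, were likewise detected only on the colon arrays (3.99 ± 0.73 and 3.92 ± 0.79).

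The arms of a precursor tended to move together. Over precursors with both arms tested, the log2 changes of the 5p and 3p arms correlated at r = 0.519 (46 pairs, permutation p = 2e-04, adjusted 6e-04, rho 0.547) for microglia against colon, 0.487 (49 pairs, p = 5e-04, adjusted 0.00075, rho 0.46) for microglia against liver and 0.406 (48 pairs, p = 0.02, adjusted 0.02, rho 0.464) for colon against liver macrophages, 3 relations in all and across miRNAs, which are not independent replicates. Where both arms were called, 9 of 10 pairs against colon and 12 of 16 against liver macrophages went the same way. The exceptions were miR-328 in both comparisons (5p -1.79 and 3p 1.64 against colon, -2.44 and 2.02 against liver macrophages) and, against liver macrophages, miR-150 (5p -6.39, 3p 3.32), miR-664 (-1.20 and 1.69) and miR-99b (1.10 and -2.25).

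Epithelial miRNAs appeared on 1 of the microglia arrays: 9 list members were higher by over 1 log2 unit on replicate 1 than on replicate 2 (miR-203-3p, at 5.62 and 5.58 against a colon mean of 4.32, was not), and on replicate 1 the 9 lay a median of 2.15 log2 units below the colon mean (range 1.99 to 2.38), or at 22.5% of the colon level. Lower sensitivity of the array of replicate 2 is argued against, since that array detected 30 more miRNAs. Epithelial RNA in replicate 1 could give the constant gap, whose SD was 0.129 over the 9 members against 1.38 over 259 other miRNAs. The gate on CD45 and CD11b should remove epithelial cells. Yet the colon samples, also gated on these markers, carried the 9 miRNAs at higher levels. RNA carried over from the colon macrophage samples could give the same gap but would put miR-511-3p, not detected on replicate 1, at 6.96 (adjusted p = 0.0164). It would also put miR-223-3p at 10.60, against 8.27 measured, and miR-143-3p, not detected there, at 4.69. Both lay below the mixing level without passing the same test (adjusted p = 0.107 and 0.0675). miR-511-3p was the 1 that passed among 213 other miRNAs in a 1-sided test that replaced 2 earlier criteria once their outcomes were known (7.98% of miRNAs more than 1 log2 unit below the mixing level, which by that criterion excluded carry-over, and 0 below by more than the largest replicate difference of 5.27). The rule, also set after the data were seen, asked for at least 3 such miRNAs before carry-over was argued against. With 1 passing, the test does not decide, and carry-over stays open. No biological explanation was tested because both arrays are of one group.

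miR-122-5p was measured on both microglia arrays (8.11 and 7.30) at 7.51% of its liver level, and on neither colon array. Carry-over of RNA from the liver macrophage samples could bring it: 0 of 144 other liver miRNAs lay below the mixing level in the 1-sided test, which was kept after the same change of criteria (3.47% more than 1 log2 unit below, and 0 beyond the largest replicate difference). Still, 5 lay more than 1 log2 unit below it, among them miR-126-3p (a mean of 3.40 with replicate 2 at the floor, 7.87 from mixing) and miR-511-3p (not detected, 4.95 from mixing). None of the 5 was detected on replicate 2, where miR-122-5p lay 4.14 log2 units below its liver mean. The test was run on the mean of both microglia arrays and does not use this, so these data leave carry-over open. Hepatocyte RNA cannot be told apart from other sources either, because the lowest level that it would give miR-192-5p or miR-194-5p on replicate 2 lies 0.483 log2 units above the lowest detected signal. Expression of miR-122 by microglia themselves was not tested and stays open. The gate on CD45 and CD11b should remove hepatocytes. Yet the liver samples, also gated on these markers, carried miR-122-5p at a higher level, so the gate does not decide between these sources.

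miRNAs with numbers of 1000 or above were catalogued late and are often poorly characterised. They made up 36 of the 72 miRNAs lower in microglia than in both other populations, against 74 of the 275 others tested (26.9%). The 2-sided Fisher's exact p was 0.000326, miRNAs not being independent replicates. Of the 58 higher ones 8 had such numbers (13.8%). The scaling of the arrays is argued against as the whole cause, since the highest exact p over 5 other scalings was 0.00589. Whether signals near the detection limit contribute was not settled. Among miRNAs brighter than the median the shares were 13 of 27 (48.1%) and 43 of 146 (29.5%, 2-sided Fisher's exact p = 0.073). Among all tested they were 50% and 26.9%. The miss was first to count for this explanation, a rule dropped once the p was seen. A missed threshold shows neither that the difference is gone nor that it holds. Probe sequences were not used here, so binding of other RNA to these probes was not tested. A biological difference between microglia and the other macrophages stays open as well.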
